A study of Mus musculus with 12 samples.

How the data were processed

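RNA was sequenced from plasma cells sorted from the bone marrow of BLTcre.mcl1fl/+ reporter mice on a C57BL/6 background. Per the labels' series description, tamoxifen switched on a human CD4 reporter, and human CD4+ cells (called marked here) and human CD4- cells (unmarked) were sorted 60 and 270 days later. There are 12 libraries, 3 for each of 4 groups. Per the labels' protocols, RNA was isolated with RNeasy Micro kits and libraries were made with the TruSeq RNA kit. Per the submitters' processing notes, the genome build was GRCm38 and limma was used, with no version or role given. The aligner, the read counter, the gene annotation and the sort gates are not given in the sources used here.

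The authors' tables hold 4 units. The deposited table for clustering gives counts, whole reads for 230 genes in the 12 libraries. Per the file headers, 2 comparison tables give CPM (reads scaled to the same total) in each library, for 14219 genes (day 60 marked against unmarked) and for 265 genes (day 270 marked against day 60 unmarked). The authors' log2 fold changes against day 60 unmarked cells and a mean log2 expression stand beside them, and so do the authors' p-value and FDR per gene. CPM columns of the larger table sum to the same total with no further scaling. Multiplying CPM by 1 total per library gave back the reads. All 151331 values under 1000 reads lay within 0.05 of a whole number (largest deviation 0.00801), and the 230 genes of the count table were matched in 100% of cells. The totals were 7449468 to 15943547 reads per library. These cover the genes of the table, which holds Jchain and no immunoglobulin chain gene, so they are not the full sequencing depth. Intervals and floors cover counting error only. Replicates varied more than counting error, by a chi-square per degree of freedom of at least 14.2 between libraries of a group.

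Some choices were made before the data were examined: the 6 comparisons, the test for each unit, the threshold, the gene lists, the naming rule and most alternatives. The design set edgeR for tables of counts and limma on log2(value + 0.5) for normalised values. Since the table of all genes is in CPM, the test was limma 3.58.1 with a trended prior on log2(CPM + 0.5), in R 4.3.3. All 12 libraries entered with 1 coefficient per group and no block, leaving 8 residual degrees of freedom. filterByExpr of edgeR 4.0.16 on the recovered reads (minimum count 10, at least 3 libraries) kept 12704 genes and removed 1515. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold minimum. Tests were two-sided unless stated. Gene positions are from GENCODE M21, which held 14165 of the 14219 identifiers, and 19 symbols turned into dates by a spreadsheet were restored from it.

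Within a day, a marked and an unmarked library share a specimen number in the labels. Correlations of residuals between libraries of 1 specimen had a median of 0.0556 (range -0.0109 to 0.115, 6 pairs), and those between specimens had a median of -0.0194 (range -0.104 to 0.0301, 12 pairs). The specimen was used as a block in an alternative, and its value is given where it changed a count by more than 1.5 times. In comparisons of 2 groups from different days the block was the replicate number instead, which joins different specimens. Replicate 1 of every group has neighbouring library numbers, apart from the other libraries. Each such set holds all 4 groups. Among the libraries other than replicate 1, every unmarked library has a lower number than every marked one. Library number and marking cannot be told apart there. The signs within the replicate 1 pairs are given.

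Named genes were chosen by a fixed rule: called genes with 1 sign in every pair (between days, every library beyond the other group's mean), the 12 largest rises and the 12 largest falls with at least 1 CPM in the higher group; passing members of lists; and Mcl1, Prdm1, Irf4, Xbp1, Sdc1, Tnfrsf17, Bcl2, Cxcr4, Cd93, Ly6a, H2-Aa, Cd74 and Mki67 whatever their values. Unnamed gene models were counted and not named. A gene named outside the rule is said to be so.

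Of 26 gene lists, 24 could be tested. They cover plasma cell identity, MHC class II, B cells, cell cycle, unfolded protein response, Bcl2 family, NF-kB and TNF receptors, adhesion and migration, interferon response, immediate early genes, autophagy, mitochondrially encoded genes, glycolysis, heat shock, TGF-beta and Klf quiescence genes, inhibitory receptors, and markers of neutrophils, monocytes and macrophages, T and NK cells, erythroid cells, megakaryocytes, plasmacytoid and other dendritic cells, stroma, and pro-B and pre-B cells. Markers of basophils and mast cells had 0 members in the table, and immunoglobulin constant regions had 1 of 13, Jchain. Lists were tested with camera of limma at a preset correlation of 0.01, adjusted over 144 tests, then with an estimated correlation and with fry.

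The alternatives were DESeq2 1.42.0, limma-voom, other filters and pseudocounts, fits of the compared libraries alone, the specimen block, a specimen correlation, Jchain left out, a fold minimum, and each library left out. After the data were seen, TMM scaling, edgeR quasi-likelihood tests, removal of features resembling ribosomal RNA, library quality weights, removal of marked libraries 2 and 3 of day 270, and comparisons pooled over days or populations were added. Random lists (10000) were matched on mean expression, each member drawn from the genes nearest to it. The test was also tried on simulated reads with known fold changes. Mcl1 and library measures were compared with exact permutation tests between groups of 3 (smallest p 0.1) or exact sign-flip tests over 6 pairs (smallest p 0.03125).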

Results

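Transcript levels were measured in 6 libraries of marked and 6 of unmarked bone marrow plasma cells, 3 at day 60 and 3 at day 270 for each population. Marked cells are those that carry the reporter switched on by tamoxifen, so that the marked pool at day 270 is the one with the longest time since marking. The libraries held 7449468 to 15943547 reads. Marked libraries 2 and 3 of day 270 had the fewest genes with a read, 11022 and 11301, and library 2 had 29.5% of its reads on features resembling ribosomal RNA and 7.90% on Jchain. Marked library 2 of day 60 had 11.4% of its reads on features resembling ribosomal RNA. Values below are mean CPM ± SD (n = 3 libraries), and log2 fold changes are given with the standard error from limma. Relative to TMM scaling, the scaling by total reads used here moved the median of all genes by -0.12 at each day (marked minus unmarked), and by 0.10 and 0.11 in the marked and the unmarked cells between days.

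The comparison of marked with unmarked cells at day 60 asks how plasma cells that were present at marking differ from the unmarked pool. Marked cells had lower RNA of MHC class II genes, which present antigen on B cells. H2-Aa (ENSMUSG00000036594, GRCm38 chromosome 17, 34282744 to 34287823), the alpha chain of I-A, was 453 ± 15.5 CPM in unmarked and 76.6 ± 31.2 in marked cells, a log2 fold change of -2.63 ± 0.32 (adjusted p 7.18e-04). Its partner H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419) went from 1111 ± 49.97 to 338 ± 67.0 CPM (-1.73 ± 0.18, adjusted p 2.02e-04). Genes of dividing cells were also lower: Top2a, a DNA topoisomerase, was 27.4 ± 5.19 CPM in unmarked and 1.63 ± 0.274 in marked cells (-3.70 ± 0.54, adjusted p 0.00503). Slc12a2, a sodium, potassium and chloride cotransporter, was higher in marked cells, with 457 ± 94.0 against 175 ± 26.8 CPM (1.38 ± 0.20, adjusted p 0.00503).

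All 36 measured cell-cycle genes had a negative log2 fold change, with a median of -1.79. Of these, 5 were called lower over all genes and 24 were lower when adjusted over the list alone. Ccna2 (cyclin A2) had a log2 fold change of -4.39, Cdc20, an activator of the anaphase-promoting complex, of -3.74, the spindle protein gene Tpx2 of -3.39 and Rrm2, a subunit of ribonucleotide reductase, of -1.81. The list's adjusted p was 5.53e-29, and 0.00928 with an estimated correlation; it was the 1 list call of 30 over the 6 comparisons that held with an estimated correlation. Mki67, the gene of the proliferation marker Ki-67, had 42.7 ± 18.0 CPM in unmarked and 18.6 ± 9.09 in marked cells and did not pass (adjusted p 0.532).

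Among 11 MHC class II genes, 3 were called lower (H2-Aa, H2-Ab1, H2-Eb1) and 8 were lower when adjusted over the list alone. The list's median was -1.48 (adjusted p 4.30e-09, and adjusted p = 0.154 with an estimated correlation). Cd74, the invariant chain, had a log2 fold change of -0.38 (adjusted p 0.858). The B cell list fell (adjusted p 8.44e-04, and adjusted p = 0.260 with an estimated correlation), with 3 of 22 members called lower and 5 when adjusted over the list alone. Fcmr, the Fc receptor for IgM, went from 306 ± 67.9 to 95.6 ± 13.1 CPM, and Cd79a, a signalling chain of the B cell receptor, from 820 ± 109 to 417 ± 41.3. Ms4a1, which encodes CD20, was at 216 ± 32.8 CPM in unmarked and 212 ± 26.4 in marked cells; it was chosen after its values were seen.

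Further falls included Slamf6 (43.2 ± 14.7 to 4.56 ± 2.89 CPM) and Cd2, both surface receptors of lymphocytes, Ltb (lymphotoxin beta) and Vim (vimentin). Cd2 had an adjusted p of 0.0395, and of 0.0584 with TMM scaling, and with the specimen as a block Cd2 and Mt2 were not called. Other rises were Nox1, an NADPH oxidase (55.7 ± 18.2 to 140 ± 27.7 CPM), Dsel (16.9 ± 7.71 to 58.6 ± 6.58), Spag6l (listed under an identifier that GENCODE M21 names Spag6) and the metallothionein Mt2 (175 ± 57.8 to 387 ± 99.6). Adhesion and migration genes fell as a list (adjusted p 0.00144, and adjusted p = 0.856 with an estimated correlation), with 0 of 25 called by limma and 6 lower when adjusted over the list alone. Inhibitory receptors fell (adjusted p 0.0126; adjusted p = 0.288 with an estimated correlation), with 0 of 11 called by limma and 2 when adjusted over the list alone (Tigit has an FDR of 0.0163 in the authors' table), and the call ended without marked library 2 (adjusted p 0.0803). TGF-beta and Klf quiescence genes fell (adjusted p 0.0343; adjusted p = 0.988 with an estimated correlation), with 0 of 18 called and 0 when adjusted over the list alone. That call ended without unmarked library 1 (adjusted p 0.128) or marked library 3 (adjusted p 0.116).

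RNA of other cells moved with the marking. Erythroid markers were higher in marked cells as a list (adjusted p 0.00504; adjusted p = 0.738 with an estimated correlation), with 5 of 9 positive and 4 negative, 0 called and 4 higher when adjusted over the list alone, and the call ended without unmarked library 1 (adjusted p 0.0679) or marked library 2 (adjusted p 0.141). The 4 adult globin genes summed to 47.9 ± 13.6 CPM in unmarked and 224 ± 113 in marked cells. Neutrophil markers were higher (adjusted p 0.0359; adjusted p = 0.988 with an estimated correlation), with 0 of 17 called and 0 when adjusted over the list alone; adjusted p was 0.747, with the direction turned, without marked library 2, and 0.210 and 0.551 without unmarked libraries 1 and 3. T and NK cell markers had a median of -1.0, and of -1.22 with 2 genes without reads in a group at their bound (adjusted p 0.0612, and 0.0177 with the specimen as a block).

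In all, limma called 24 of 12704 genes at day 60, 5 higher and 19 lower in marked cells, and 819 had an unadjusted p under 0.05. All 24 had 1 sign in the 3 specimen pairs, the replicate 1 pair included, and H2-Aa, H2-Ab1 and H2-Eb1 were called in each of 20 alternative settings. The count was 14, 3 and 6 without unmarked libraries 1, 2 and 3, and 10 and 11 without marked libraries 2 and 3. It was 38 with the specimen as a block (10 higher, 28 lower, 22 of the 24 among them), 44 with only the 6 compared libraries fitted, 119 with DESeq2 (48 higher, 71 lower) and 163 with library quality weights. The balance was 12 higher and 13 lower with limma-voom, and 12 and 22 with TMM scaling.

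**Figure D1:**
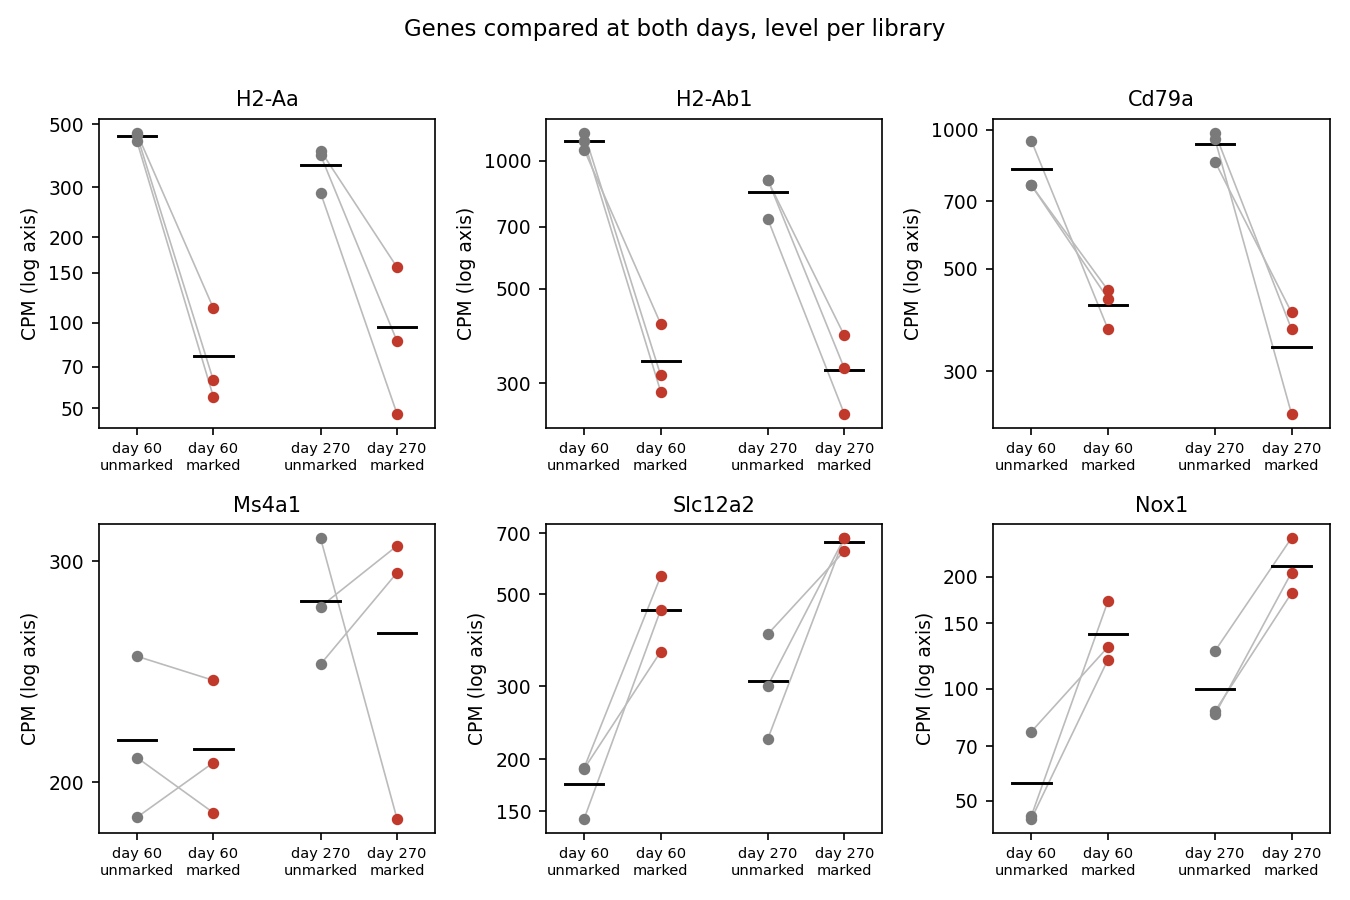
CPM of 6 genes on a log axis in unmarked (grey) and marked (red) libraries at day 60 and day 270; each point is a library, a black bar is the group mean and a grey line joins the libraries of 1 specimen. H2-Aa, H2-Ab1 and Cd79a are lower and Slc12a2 and Nox1 higher in marked libraries at both days, while Ms4a1 is at 216 and 212 CPM at day 60.

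The same comparison at day 270 asks whether marked cells still differ after 270 days. MHC class II RNA was again lower in marked cells: H2-Eb1, the beta chain of I-E, was 492 ± 82.6 CPM in unmarked and 157 ± 31.0 in marked cells (-1.65 ± 0.18, adjusted p 3.14e-04), and H2-Ab1 was 843 ± 98.6 and 323 ± 67.2 CPM. Fas, a death receptor, was 21.03 ± 5.15 CPM in unmarked and 0.986 ± 0.855 in marked cells (-4.08 ± 0.52, adjusted p 0.00115). The cytokine receptor chain gene Il2rb went from 19.9 ± 12.04 to 0.878 ± 1.52 CPM and the chemokine receptor gene Cxcr3 from 22.2 ± 11.6 to 1.95 ± 2.65. The largest rise was Enpp5, with 5.08 ± 0.872 CPM in unmarked and 37.9 ± 8.90 in marked cells (2.77 ± 0.43, adjusted p 0.00684).

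All 11 MHC class II genes were negative, 4 were called (H2-Eb1, H2-Ab1, H2-Aa, H2-Eb2) and 6 were lower when adjusted over the list alone (list median -1.34, adjusted p 2.36e-05; adjusted p = 0.283 with an estimated correlation). Of 36 cell-cycle genes 35 were negative, 0 were called by limma and 14 were lower when adjusted over the list alone. Their median was -1.20, or -1.28 with 2 genes without reads at their bound (adjusted p 4.68e-09; adjusted p = 0.146 with an estimated correlation). Outside that list, Cdca3, a gene of dividing cells, was called (10.9 ± 2.12 to 0.378 ± 0.379 CPM). Nek2, a mitotic kinase, had 2 reads over the marked libraries, a read ratio of 95.04 (95% counting interval 26.0 to 790). Of the B cell list, Cd79a (929 ± 68.3 to 338 ± 84.4 CPM) and Fcmr fell; the list did not pass (median -0.19, adjusted p 0.490).

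Inhibitory receptors fell as a list (adjusted p 0.0262; adjusted p = 0.400 with an estimated correlation), with Tigit, Pdcd1 and Ctla4 called of 11, and 5 when adjusted over the list alone. Tigit was 52.5 ± 11.3 CPM in unmarked and 12.5 ± 9.92 in marked cells, and Pdcd1, which encodes PD-1, 5.44 ± 0.131 and 0.230 ± 0.398. The list's call ended without unmarked library 3 (adjusted p 0.0602) and without marked libraries 1, 2 or 3 (0.0576, 0.0504 and 0.0777). Adhesion and migration genes fell (adjusted p 0.0142; adjusted p = 0.907 with an estimated correlation), 2 of 25 called and 8 when adjusted over the list alone, and not without marked library 2 (adjusted p 0.0616). The called members were Cxcr3 and Ccr10, a chemokine receptor gene of IgA plasma cells (110 ± 39.9 to 32.7 ± 14.2 CPM). Myc, a growth regulator, had a log2 fold change of -2.51. Fcrl5, a gene of the Fc receptor-like family, and Shcbp1 had 0 reads in the marked libraries and were at least 85.3-fold and at least 57.7-fold lower (floor of 3 counts over the group). Slc12a2 was higher (308 ± 88.4 to 666 ± 27.5 CPM), as were Nox1, Slamf9 (172 ± 19.4 to 342 ± 46.2), Cyb561 and Spns3. With the specimen as a block Pdcd1, Ctla4, Myc, Shcbp1, Cyb561 and Spns3 were not called.

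Erythroid markers were higher in marked cells (9 of 9 positive, 0 called by limma, 5 when adjusted over the list alone; adjusted p 1.12e-07, and adjusted p = 0.247 with an estimated correlation). The globin genes summed to 108 ± 70.6 CPM in unmarked and 534 ± 330 in marked cells. Neutrophil markers (adjusted p 0.0343), monocyte and macrophage markers (adjusted p 0.0142) and mitochondrially encoded genes (adjusted p 0.0343) were higher as lists, with 0 members called and 0 when adjusted over each list alone, and each had adjusted p = 0.988 with an estimated correlation. Without unmarked library 1, or marked libraries 2 or 3, these 3 lists were not called: adjusted p was 0.477, 0.562 and 0.177 for neutrophils, 0.315, 0.110 and 0.168 for monocytes and macrophages, and 0.477, 0.0815 and 0.183 for mitochondrial genes, which also had 0.0581 without marked library 1.

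At day 270 limma called 61 genes, 6 higher and 55 lower in marked cells, with 1773 at an unadjusted p under 0.05; all 61 had 1 sign in the 3 pairs, the replicate 1 pair included. Of the 61, 23 had a library without reads in the lower group. The count was 5, 16 and 6 without unmarked libraries 1, 2 and 3, 475 and 101 without marked libraries 1 and 3, and 20 without marked libraries 2 and 3 together, which left 1 marked library of day 270. It was 0 with only the 6 compared libraries fitted, 256 with DESeq2, 36 with edgeR (12 higher, 24 lower) and 129 with library quality weights.

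**Figure D2:**
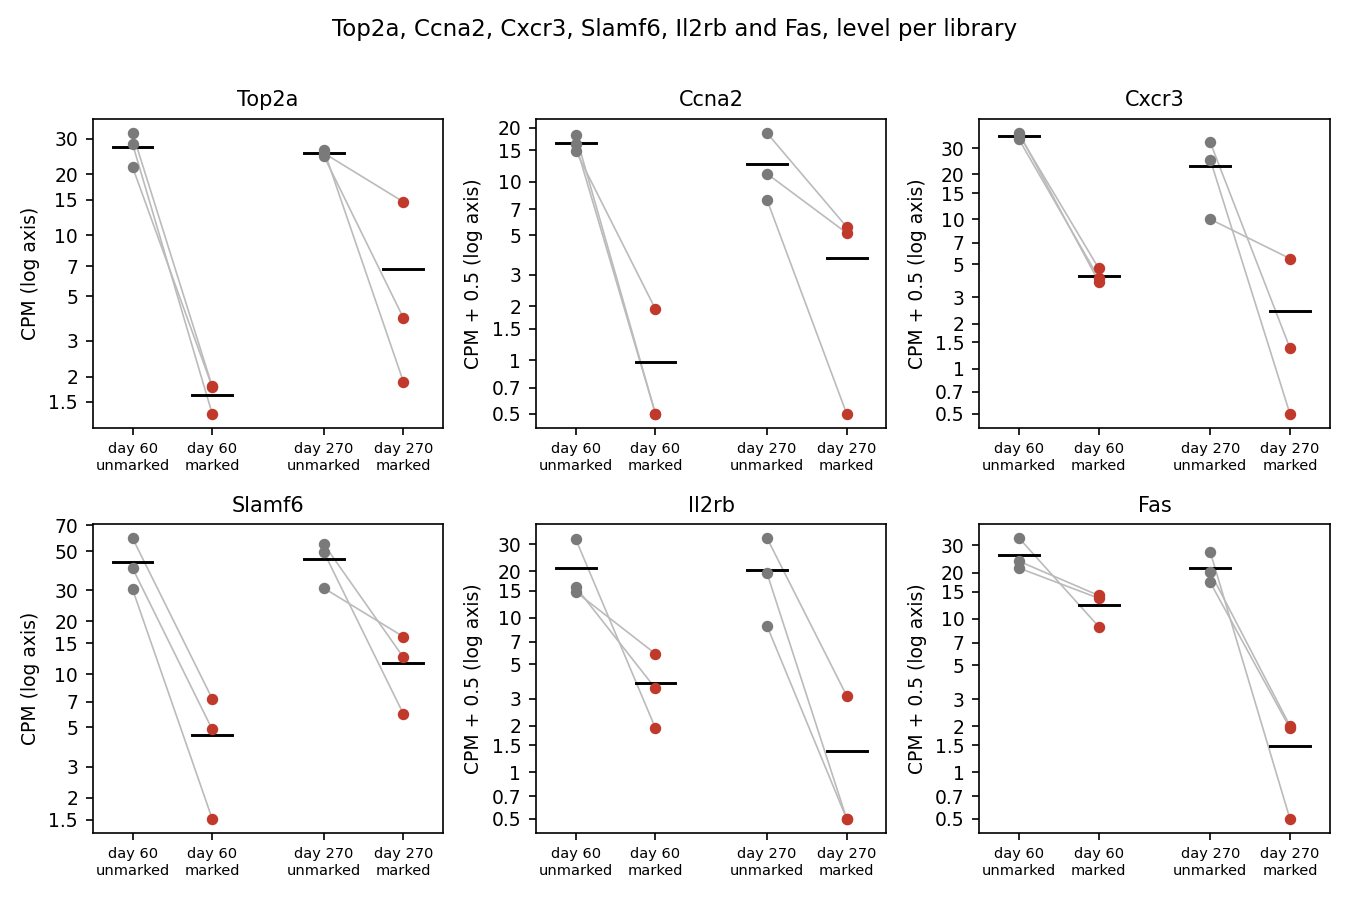
CPM of 6 genes on a log axis (CPM + 0.5 where a library has no read) in unmarked (grey) and marked (red) libraries at both days; each point is a library, a black bar is the group mean and a grey line joins the libraries of 1 specimen. Top2a is at 27.4 CPM in unmarked and 1.63 in marked cells at day 60, and Fas at 21.03 and 0.986 at day 270.

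The calls of the 2 days overlapped; they compare different libraries but share a residual variance from all 12, and with only the compared libraries fitted day 270 had 0 calls by limma to overlap. H2-Ab1, H2-Aa, H2-Eb1, Cd79a, Fcmr, Napsa, Ccnd2 and Coro1a were lower at both days, 8 genes against 0.0823 for independent lists (Fisher's exact p 5.29e-15, one-sided), and Slc12a2 and Nox1 were higher at both (2 genes against 0.00236, Fisher's exact p 1.86e-06). Napsa, Ccnd2 and Coro1a are named here outside the rule, as genes called at both days. Genes are not independent replicates and the variance is shared, so these p-values are descriptive. All 24 genes of day 60 had the same sign at day 270, and 59 of the 61 of day 270 had the same sign at day 60. Across 12704 genes the log2 fold changes of the days had a Pearson correlation of 0.341 and a Spearman correlation of 0.297.

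**Figure D3:**
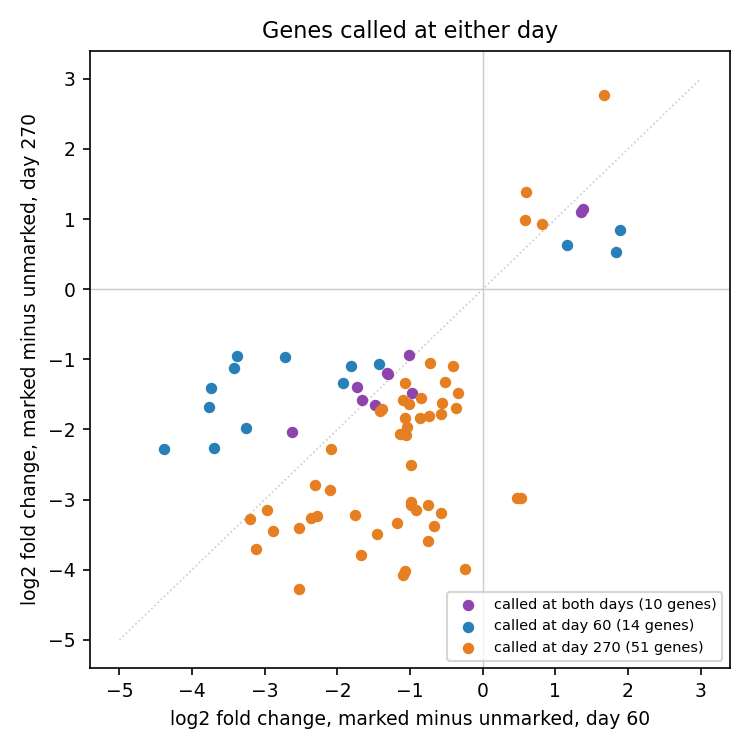
Log2 fold change of marked against unmarked cells at day 60 (horizontal) and day 270 (vertical) for the 75 genes called at either day, coloured by the day of the call; the dotted line marks equal values. Of the 75 genes, 64 are lower and 9 higher in marked cells at both days.

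A test of the difference between the days found no gene. limma called 0 genes for the interaction (387 at an unadjusted p under 0.05, smallest adjusted p 0.9999), and limma-voom and edgeR called 0 and DESeq2 5. As lists, cell-cycle genes had a positive interaction (median 0.40, adjusted p 1.15e-04; adjusted p = 0.283 with an estimated correlation), and so did erythroid markers (median 0.67, adjusted p 0.0277; adjusted p = 0.898 with an estimated correlation), with 0 members called and 0 when adjusted over each list alone. The erythroid call ended without day 60 unmarked library 2 (adjusted p 0.0965), day 60 marked libraries 1 (0.182) and 3 (0.0833), day 270 unmarked library 1 (0.510) and day 270 marked library 2 (0.469). Without day 270 marked library 1 the count of genes was 1.

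**Figure D4:**
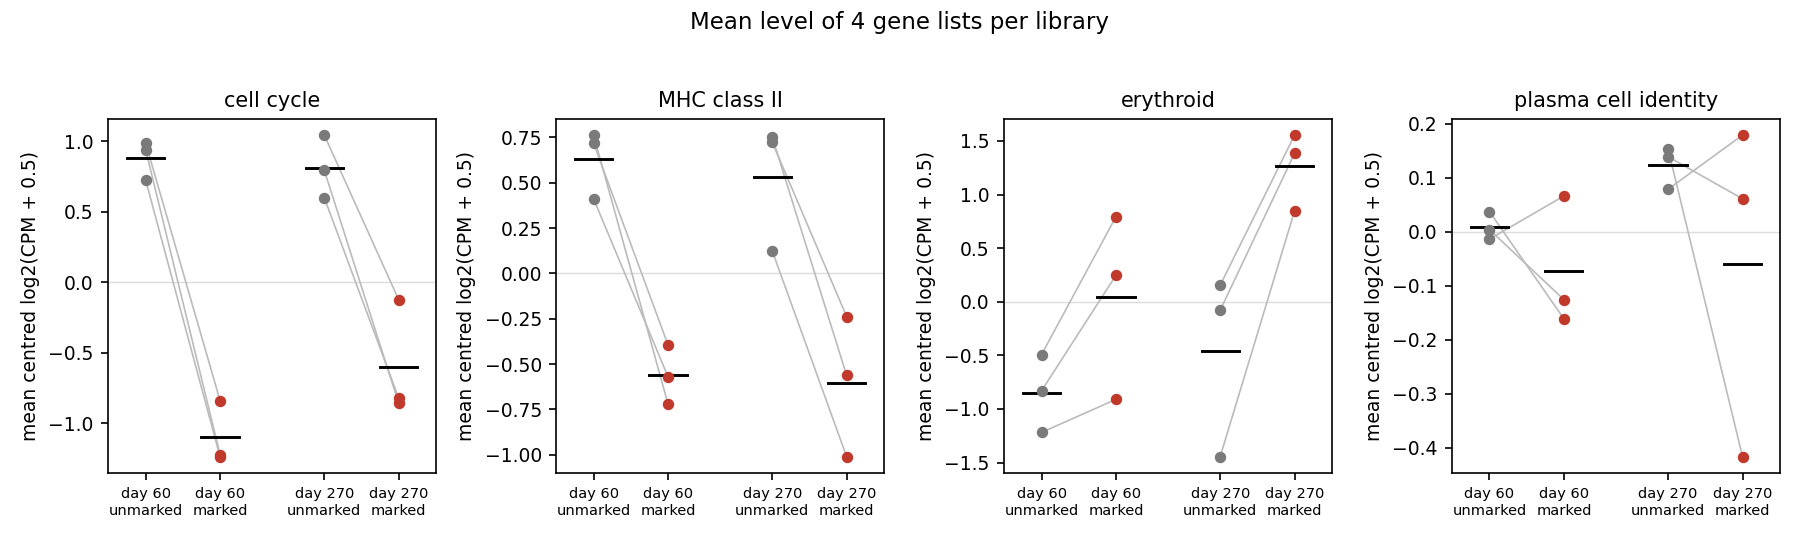
Mean centred log2(CPM + 0.5) of the members of 4 lists per library in unmarked (grey) and marked (red) cells at both days; each point is a library and a black bar is the group mean. Cell-cycle and MHC class II genes lie lower in marked libraries and the group mean of erythroid markers lies higher, with list medians of -1.79, -1.48 and 1.33 at day 60, where marked library 1 (-0.911) is below unmarked libraries 2 (-0.494) and 3 (-0.831) for erythroid markers.

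Day 270 marked cells were compared with day 60 unmarked cells in a deposited table, which sets the cells longest marked against the earlier unmarked pool. Marking and day differ together in this comparison and cannot be told apart in it. Marked cells had lower Cxcr3 (35.8 ± 1.84 to 1.95 ± 2.65 CPM, -4.54 ± 0.67, adjusted p 0.00157) and Fas (25.7 ± 6.45 to 0.986 ± 0.855 CPM, -4.36 ± 0.52, adjusted p 2.84e-04). H2-Ab1 and H2-Eb1 fell (-1.80 ± 0.18 and -1.79 ± 0.18, adjusted p 5.55e-05 for each). The largest fitted rises were Cyp2b10, a cytochrome P450 (0.430 ± 0.670 to 19.9 ± 16.7 CPM, 4.32 ± 0.71), and P4ha2, a collagen prolyl hydroxylase (0.782 ± 0.672 to 22.1 ± 5.91 CPM, 4.23 ± 0.61). Ly6a, which encodes Sca-1, rose from 1575 ± 235 to 2676 ± 332 CPM (adjusted p 0.0320).

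Of 36 cell-cycle genes, 6 were called lower, among them Cdk1, Cdc45 and Birc5, and 16 when adjusted over the list alone (median -1.49, or -1.55 with 2 genes without reads at their bound; adjusted p 2.51e-10, and adjusted p = 0.138 with an estimated correlation). Of the MHC class II list 5 of 11 were called lower and 7 when adjusted over the list alone (adjusted p 9.94e-07; adjusted p = 0.247 with an estimated correlation). Tigit, Ccr10, Myc, Fcmr, Cd79a and Blk, a kinase of B cells, were lower. Myc was not called with the replicate number as a block. Fcrl5 was at least 117-fold lower, with 0 reads in the marked libraries. Lmbr1 had 0 reads in day 60 unmarked cells and was at least 63.7-fold higher, above the ratio of means of Cyp2b10 or P4ha2. Single members of other lists rose: Pmaip1, which encodes the Mcl1-binding protein Noxa (17.7 ± 6.94 to 47.9 ± 6.51 CPM), Epcam (126 ± 36.6 to 267 ± 12.1), Ly6c2 and the lysosomal gene Lamp1. Hspa1b, an Hsp70 gene, fell from 8.45 ± 2.25 to 0.583 ± 0.903 CPM. With both populations averaged, Epcam (0.94 ± 0.15) and Cyp2b10 (3.07 ± 0.50) were also higher and Hspa1b (-2.67 ± 0.50) lower at day 270 than at day 60. Pmaip1, Ly6c2 and Lamp1 were not called there. Over both days Epcam was at 190 CPM in unmarked and 209 in marked cells.

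Erythroid markers were higher (4 of 9 called, all globin genes, and 5 when adjusted over the list alone; adjusted p 3.48e-06, and adjusted p = 0.283 with an estimated correlation), with Hbb-bs at 30.6 ± 10.1 and 287 ± 174 CPM. Monocyte and macrophage markers were higher (1 of 14 called, Vcam1, and 3 when adjusted over the list alone; adjusted p 9.46e-05, and adjusted p = 0.853 with an estimated correlation). Neutrophil markers were higher (adjusted p 0.0138; adjusted p = 0.988 with an estimated correlation), with 0 called and 0 when adjusted over the list alone. The neutrophil call ended without day 60 unmarked libraries 1 (adjusted p 0.0661) or 3 (0.174), or day 270 marked libraries 2 (0.360) or 3 (0.0777).

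In this comparison limma called 196 genes, 101 higher and 95 lower, with 1826 at an unadjusted p under 0.05; in 66 of them the lower group had a library without reads. The authors' table for this comparison lists genes at an FDR under 0.05, 126 higher and 139 lower, and 165 of them were called here, while their table for day 60 has 28 such genes (12 higher, 16 lower), 16 of them called here. limma-voom with TMM on all genes gave the authors' log2 fold changes to within 8.08e-10 and 1.25e-07. The count was 115, 75 and 51 without day 60 unmarked libraries 1, 2 and 3, 573 without day 270 marked library 1, and 40 without marked libraries 2 and 3 of day 270 together. It was 7 with only the 6 compared libraries fitted, 573 with DESeq2, 330 with TMM scaling and 354 without features resembling ribosomal RNA (238 higher, 116 lower). Without Jchain 76 were higher and 139 lower.

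Between day 60 and day 270 limma called 4 genes in marked cells. The days hold different specimens, so time after tamoxifen cannot be told apart from other differences between specimens, mouse age among them. In them Scd1, a fatty acid desaturase, rose from 14.0 ± 5.21 to 54.6 ± 10.4 CPM (1.97 ± 0.32, adjusted p 0.0314), Slamf9 from 143 ± 15.1 to 342 ± 46.2 (adjusted p 0.0264) and Hepacam2 from 73.9 ± 11.3 to 210 ± 61.0 (adjusted p 0.0264, and 0.0532 with TMM scaling), while Fas fell from 11.7 ± 2.90 to 0.986 ± 0.855 CPM (adjusted p 0.0264). In unmarked cells Scd1 was at 38.5 ± 21.1 and 84.1 ± 0.621 CPM and Fas at 25.7 ± 6.45 and 21.03 ± 5.15 CPM (not called by limma). With both populations averaged, Scd1 (1.61 ± 0.23), Slamf9 (1.05 ± 0.13) and Hepacam2 (1.29 ± 0.16) were higher at day 270, and Fas was not called. For the interaction limma called 0 genes, so these changes are not shown to be particular to marked cells. As lists in marked cells, monocyte and macrophage markers rose (median 1.34, adjusted p 0.00232; adjusted p = 0.898 with an estimated correlation; 0 called by limma, 5 when adjusted over the list alone). Erythroid markers rose (median 1.33, adjusted p 0.00920; adjusted p = 0.817 with an estimated correlation; 0 called, 0 when adjusted over the list alone). Cell-cycle genes rose (median 0.38, or 0.39 with 3 genes without reads at their bound, adjusted p 0.0114; adjusted p = 0.733 with an estimated correlation; 0 called, 1 when adjusted over the list alone).

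These list calls leaned on single libraries. Without day 270 marked library 2, adjusted p was 0.0608 for monocytes and macrophages, 0.332 for erythroid markers and 0.1003 for the cell cycle. Without day 60 marked library 1 it was 0.0635 for erythroid markers, and without day 60 marked library 3 or day 270 marked library 1 it was 0.122 and 0.223 for the cell cycle. At an unadjusted p under 0.05 there were 1225 genes. Of 10 splits of these libraries, the real one included, 4 reached as many, and the highest other reached 2509. The 4 called genes were 0 without day 60 marked libraries 2 or 3, 151 without day 270 marked library 1 and 1 without day 270 marked library 3. Without Jchain limma called 1 gene, the fall of Fas, and 0 higher, so the rises of Scd1, Slamf9 and Hepacam2 were not called. DESeq2 called 128 genes, edgeR 2 and limma-voom 0.

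In unmarked cells between the days, limma called 0 genes (378 at an unadjusted p under 0.05, smallest adjusted p 0.154), edgeR and limma-voom 0, DESeq2 11, and limma with library quality weights 79 (76 higher, 3 lower). Monocyte and macrophage markers rose as a list (adjusted p 0.0160; adjusted p = 0.988 with an estimated correlation), as did the 4 megakaryocyte markers (adjusted p 0.0475; adjusted p = 0.898 with an estimated correlation). Mitochondrially encoded genes fell (adjusted p 0.0288; adjusted p = 0.988 with an estimated correlation) and MHC class II genes fell (median -0.15, adjusted p 0.0370; adjusted p = 0.898 with an estimated correlation). Each of the 4 lists had 0 members called and 0 when adjusted over the list alone, and each call ended without single libraries: unmarked library 3 of day 60 gave 0.706, 0.187 and 0.258 for monocytes, megakaryocytes and mitochondrial genes, and unmarked library 2 of day 270 gave 0.790 for MHC class II, 0.614 for megakaryocytes and 0.0768 for monocytes. Day 60 unmarked library 1 gave 0.215 for megakaryocytes and 0.156 for MHC class II, day 60 unmarked library 2 gave 0.135, 0.238 and 0.108 for monocytes, mitochondrial genes and MHC class II, day 270 unmarked library 1 gave 0.820 for mitochondrial genes, and day 270 unmarked library 3 gave 0.350 and 0.183 for monocytes and megakaryocytes. Without day 60 unmarked library 1, 8 genes were called.

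Genes that define plasma cells did not pass in any of the 6 comparisons. At day 60 Xbp1, a transcription factor of secretory cells, was at 5023 ± 588 CPM in unmarked and 4520 ± 515 in marked cells, Sdc1 (CD138) at 2008 ± 116 and 2010 ± 241, and Tnfrsf17 (BCMA) at 313 ± 49.4 and 374 ± 26.7. Prdm1, Irf4, Bcl2, Cxcr4 and Cd93 were also not called. The plasma cell identity list had medians from -0.22 to 0.10 and a smallest adjusted p of 0.807. The smallest adjusted p over the 6 comparisons was 0.809 for the unfolded protein response, 0.331 for the Bcl2 family, 0.495 for NF-kB and TNF receptors, 0.0548 for the interferon response, 0.229 for immediate early genes, 0.1003 for autophagy, 0.546 for glycolysis and 0.546 for heat shock. For markers of other cells it was 0.0612 for T and NK cells, 0.812 for dendritic cells, 0.544 for stroma and 0.607 for pro-B and pre-B cells.

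Mcl1, a survival gene with 1 floxed allele in these mice, was 520 ± 32.2 CPM in unmarked and 414 ± 85.6 in marked cells at day 60, and 555 ± 31.7 and 438 ± 66.7 at day 270. Marked cells were lower in 6 of 6 specimen pairs, at a mean of 78.5% of the unmarked level (exact sign-flip p 0.03125, the smallest that 6 pairs allow). The sign-flip test was not among the tests set for Mcl1 beforehand. With both days pooled and the specimen as a block, limma did not call Mcl1. Within a day it did not pass either: limma's adjusted p was 0.784 at day 60 and 0.357 at day 270, and the exact permutation p was 0.2 and 0.1 (n = 3 against 3, where 0.1 is the smallest possible). Loss of the floxed allele in marked cells was not measured here. If it was lost, marked and unmarked cells differ in Mcl1 gene dose as well as in time since marking. The comparisons of marked with unmarked cells cannot tell these apart.

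**Figure D5:**
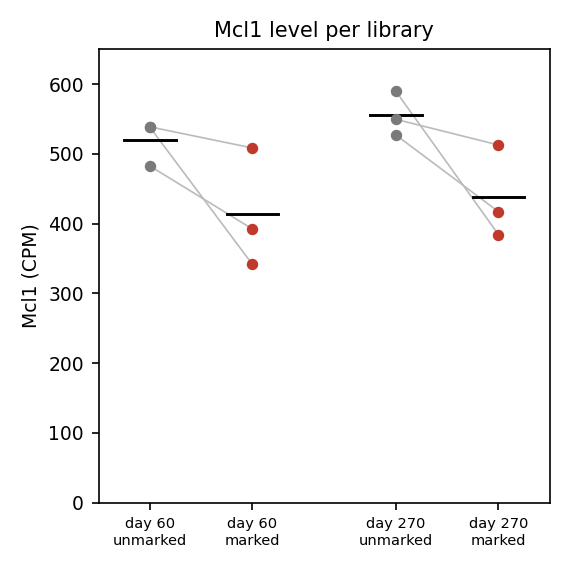
CPM of Mcl1 per library on an axis from 0, in unmarked (grey) and marked (red) cells at both days; each point is a library, a black bar is the group mean and a grey line joins the libraries of 1 specimen. The marked library is lower in all 6 pairs.

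The authors' count table of 230 genes was made for clustering, and 139 of its genes are in their table of day 270 marked against day 60 unmarked cells. Average linkage on 1 minus the Pearson correlation put 12 of 12 libraries on the side of their own population with these genes. With all 12704 genes 7 of 12 were on that side, because the split set marked library 2 of day 270 alone against all other libraries. That score reflects 1 outlying library and does not show whether the populations mix. The rule by which the 230 genes were chosen is not given in the sources used here, so the split on these genes is not independent evidence of a difference.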

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

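The tests of scaling, of erythroid RNA, of a lower plasma cell share and of few genes detected at day 270 were chosen only after the result was seen, and the rule for scaling at day 270 was made stricter after its outcome. The test of NK cells and the look at which labels the splits exchange were also chosen after. The tests of low detection for cell-cycle genes and of T cells, and the splits of the 6 comparisons, were set before. The marked against unmarked difference itself differed between the days for 2 gene lists by camera. Cell-cycle genes had an interaction median of 0.40 on the log2 scale (day 60 -1.79, day 270 -1.20), and erythroid markers had 0.67 (day 60 1.33, day 270 2.03). Neither held with an estimated correlation (adjusted p = 0.283 and adjusted p = 0.898), and limma called 0 single genes for the interaction, with 387 at an unadjusted p under 0.05, 0 by limma-voom and edgeR and 5 by DESeq2.

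Cell-cycle RNA was lower in marked cells, and so were the receptor genes Cxcr3, Il2rb, Slamf6 and Tigit, which were picked because they fell and form no tested list. For the cell-cycle list, low detection alone was argued against: 0% of 10000 random lists matched on mean expression had a median as low at day 60. The list's median was -1.71 with TMM scaling. With TMM all 4 receptor genes were still called over both days with falls of at least the -2.06 of Tigit (-2.19 without TMM), and low detection was not tested for them. Relative to TMM, scaling by total reads moved the median of all genes by -0.12 at each day, far less than these falls. The choice between these scalings is thus argued against as their source. The rules for scaling were set after the data were seen, and a shift of that size left them little room for another outcome. T cells in the unmarked gate were argued against as the source of the receptor RNA by the T cell receptor complex genes that were tested. Cd3d, Cd3g and Trac had a mean of 2.27 CPM in unmarked libraries, 5.94% of that of the 4 receptor genes (38.2 CPM). Cd3e, Trbc1 and Trbc2 of the same set were not among the genes tested. NK cells in the unmarked gate cannot be told apart: of 5 fixed markers only Nkg7 and Gzma were measured, at 2.91% of the receptor level. Prf1 (14.4 to 2.03 CPM) and Klrb1 (2.59 to 0 CPM), named outside the rule, fell over both days. By camera the T and NK list at day 60 had an adjusted p of 0.0612, and of 0.0177 with the specimen as a block. NK cells stay open for the receptor genes. A biological difference that the design names, between cells marked earlier and the unmarked pool, stays open for both and was not tested. It may include a difference in Mcl1 gene dose.

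Haemoglobin RNA was 4.69-fold higher in marked than in unmarked libraries over the 6 pairs, higher in 6 of 6 (exact sign-flip p 0.03125, and 0.188 adjusted over 12 library measures). RNA of erythroid cells is a candidate explanation: over both days 0.88% of matched random lists had a median as high as the 5 erythroid genes other than globins. These random lists do not carry the correlation between erythroid genes. By camera with an estimated correlation, the whole erythroid list had an adjusted p of 0.0677 over both days. At day 60 alone the globins were higher, and the negative members of the erythroid list were all among these 5. Most of the 5 were thus lower in marked cells at day 60. Alas2, 2.02-fold higher on average over the 6 pairs and above 0 in 5 of them, had an exact sign-flip p of 0.156. A lower share of plasma cells in the marked libraries would raise markers of other cells alike, and it cannot be told apart: haemoglobin exceeded neutrophil granule RNA with an exact sign-flip p of 0.0625 and C1q RNA with one of 0.03125, and both were required to fall under 0.05. A rule on C1q alone, tried after these values were seen, would have argued against it; it was dropped because it was picked knowing the outcome. Sort gates are not given in the sources used here, and no biological explanation was tested.

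At day 270 more genes were called lower than higher in marked cells, 55 against 6 (90.2% of the 61 calls). Scaling of the libraries cannot be told apart as a source: with TMM-scaled limma 67 were lower and 22 higher (75.3% lower), both more than before, while edgeR gave 24 and 12 (66.7%), limma-voom 25 and 25 (50%) and DESeq2 162 and 94 (63.3%), which change the test as well as the scaling. Few genes detected in marked libraries at day 270 was set against it through the other day: 0% of matched random lists had a day 60 median as low as that of the 55 genes that fell (-1.07). That argues that low detection in those libraries is not the whole of it, although 23 of the 61 calls have a library without reads in the lower group. A biological difference between the populations stays open and was not tested.

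Other splits of the same libraries were also fitted. The 10 splits of 3 against 3 are too few for a share under 0.05, and in each case 1 split, the real one, gave as many genes except where stated: 24 genes for day 60 (highest other 0), 61 for day 270 (highest other 0), 196 for day 270 marked against day 60 unmarked (highest other 0), and 4 for marked cells between days (highest other 2). For unmarked cells between days the real split gave 0 genes, as did the others, so that 10 of 10 gave as many. Within each day, 3 of the other splits part all specimen pairs as the real one does, and they gave 0 genes. For the difference between days the real split gave 0 and 100 of 100 gave as many. The highest other gave 234, which points to a structure of the samples: it exchanges the labels of all 6 libraries of day 270 and of 0 of day 60, so that by construction it adds the marked against unmarked differences of the 2 days.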

How the results depend on the processing

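TMM scaling, edgeR, removal of features resembling ribosomal RNA, quality weights, the removal of marked libraries 2 and 3 of day 270 and each library left out for Mcl1 were chosen after the data were seen. Counts are given in the order day 60, day 270, day 270 marked against day 60 unmarked, and marked, unmarked and interaction between days (24, 61, 196, 4, 0, 0). DESeq2 gave 119, 256, 573, 128, 11 and 5. With only the compared libraries fitted the first 4 were 44, 0, 7 and 0. Marked cells between days gave 0 with limma-voom, 1 with limma-voom and a specimen correlation together, 1 without Jchain and 2 with edgeR. edgeR gave 36 at day 270, and the specimen block gave 38 at day 60. The third count was 330 with TMM and 354 without features resembling ribosomal RNA. Quality weights gave 163 at day 60, 129 at day 270 and 79 in unmarked cells. Without marked libraries 2 and 3 of day 270 the counts were 20, 40 and 0 for the comparisons that use them; the lone library is assumed to vary like the others. Leaving out 1 library gave 3 to 19, 5 to 475, 51 to 573, 0 to 151, 0 to 8 and 0 to 1. The cause of these changes was not tested. Fits of fewer libraries have fewer residual degrees of freedom, which does not account for the rise from 24 to 44 at day 60. The marked libraries of day 270 varied most: their mean correlation within the group was 0.869 to 0.892, against 0.946 to 0.960 elsewhere. The 61 calls of day 270 use a residual variance shared with the less variable groups.

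The 30 list calls became 1 with an estimated correlation, 10 with directional fry (8 of the 30, and 0 of its calls higher against 16 before), 17 without those 2 libraries (15 of the 30), and 15 to 30 with 1 library left out. Neutrophil markers turned direction at day 60 without marked library 2 (adjusted p 0.747, range over libraries left out 8.90e-08 to 0.747), and without marked libraries 2 and 3 of day 270 at day 270 (0.797) and against day 60 unmarked cells (0.930); the cause was not tested. At an FDR of 0.01 the authors' tables have 11 and 70 genes. Other filters, pseudocounts and the fold minimum kept each count within 1.5 times, the Mcl1 ratio stayed at 75.7 to 86.6%, and the clustering on the 230 genes put 100% of libraries on their side. Of named genes that were called, 0 changed sign in any setting. In reads simulated at the depths and replicate numbers of these libraries the test called 22% of genes with a 2-fold change at day 60 and 79% with a 4-fold change. For the interaction it called 4% and 53%. The simulation gave each gene the same spread in all groups, while the marked libraries of day 270 varied more. These shares may therefore be too high where those libraries are compared. Other depths were not simulated.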

Other observations

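All tests in this part were chosen after the data were seen. With both days pooled and the specimen as a block, 236 genes differed between marked and unmarked cells, 45 higher and 191 lower. Beyond the genes above, marked cells had lower Atp1b1, a subunit of the sodium pump (-2.82 ± 0.31), lower Pim2, a survival kinase (-0.89 ± 0.15), and lower S1pr1, a receptor for sphingosine 1-phosphate (-2.39 ± 0.50), the integrin gene Itga4 (-0.81 ± 0.16) and Il2ra (-2.76 ± 0.47), while the receptor genes Il13ra1 (0.61 ± 0.12) and Ltbr (1.86 ± 0.43) were higher. Prf1, which encodes perforin, was also lower (-2.81 ± 0.42). Higher were Enpp5 (2.22 ± 0.34), the tight junction gene Cldn7 (1.08 ± 0.18), Fcer1g (1.03 ± 0.21) and the Polycomb gene Bmi1 (0.65 ± 0.12). These genes were chosen after their values were seen. All 36 cell-cycle genes were negative, 15 were called and 29 were lower when adjusted over the list alone (adjusted p 4.53e-20, and 0.0235 with an estimated correlation). MHC class II genes fell too, 6 of 11 called and 7 when adjusted over the list alone (adjusted p 3.77e-08, and 0.0235 with an estimated correlation). Of the markers of other cells 3 lists were higher in marked cells: erythroid markers, 4 of 9 called (adjusted p 5.49e-12; adjusted p = 0.0677 with an estimated correlation), with Hbb-bs at the smallest p of all genes, neutrophil markers (adjusted p 6.20e-05; adjusted p = 0.444 with an estimated correlation) and monocyte and macrophage markers (adjusted p 0.00627; adjusted p = 0.616 with an estimated correlation), the last 2 with 0 members called by limma. The other lists of such markers had negative medians and did not pass: T and NK cells (-0.76), megakaryocytes (-1.04), pro-B and pre-B cells (-0.53), dendritic cells (-0.35) and stroma (-0.16). By camera adhesion and migration genes (median -0.46, adjusted p 7.34e-04) and inhibitory receptors (-0.68, adjusted p 0.0107) fell. Mitochondrially encoded genes (0.12, adjusted p 0.0214) and autophagy genes (-0.03, adjusted p 0.0457) ranked above other genes. With an estimated correlation these lists had adjusted p of 0.444, 0.342, 0.616 and 0.616. The B cell list fell (-0.46, 20 of 22 negative, 5 called; adjusted p 0.0457, and adjusted p = 0.342 with an estimated correlation).

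The pooled count was 369 with TMM scaling (155 higher, 214 lower) and 242 with edgeR (123 higher, 119 lower, 163 of the 236 among them). It was 117, 88 and 130 without pairs 1, 2 and 3 of day 60, and 102, 213 and 393 without pairs 1, 2 and 3 of day 270. Swapping the populations within pairs gave 32 arrangements, and 1 of them, the real one, reached 236 (a share of 0.03125). The highest other gave 5. This share is the smallest that 32 arrangements allow, and the comparison was chosen after the data were seen. The swaps argue against chance but do not exclude it.

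Between days, with the 2 populations averaged and libraries of 1 specimen taken as independent, 23 genes were higher and 1 lower at day 270. Higher were the desaturases Scd1 (1.61 ± 0.23) and Scd2 (0.82 ± 0.14), Axl, a receptor tyrosine kinase (1.85 ± 0.27), Hmox1, haem oxygenase (1.23 ± 0.20), Bcl2l1, which encodes Bcl-xL (1.52 ± 0.27), Hepacam2 (1.29 ± 0.16) and Slamf9 (1.05 ± 0.13). Hspa1b was lower (-2.67 ± 0.50). These genes were chosen after their values were seen. Monocyte and macrophage markers were higher as a list (adjusted p 6.32e-04; adjusted p = 0.874 with an estimated correlation; 6 when adjusted over the list alone). The 24 genes were 47, 6 and 4 without day 60 unmarked libraries 1, 2 and 3, 3 without day 60 marked library 2, 5 and 13 without day 270 unmarked libraries 2 and 3, and 56 and 58 without day 270 marked libraries 1 and 2. Of 10 splits of the specimens, too few for a share under 0.05, 1 gave as many and the highest other gave 2.

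Genes higher in marked cells may also be higher at day 270 than at day 60 in both populations. Since the days hold different specimens, time after tamoxifen cannot be told apart here from mouse age or other differences between specimens. The 45 genes had a median day difference of 0.59 in marked cells and of 0.63 in unmarked cells (0.73 with both averaged), and in each case 0% of 10000 matched random lists had one as high. Without the globins it was 0.60 in unmarked cells. Of the 45, 40 had a positive difference between days, and B3galnt1, Clic5, Lmo2, Mt2, Slamf9 and Spag6l (Spag6 in GENCODE M21), 6 genes against 0.0815 for independent lists, were called in both. The genes were selected on the same libraries, so this is a hypothesis. The 191 genes lower in marked cells had a median day difference of -0.03, and 0% of matched random lists had one as low (random median 0.07).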
